A study of Drosophila melanogaster
Homo sapiens and Homo sapiens with 11 samples.

How the data were processed

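The series holds 11 samples of NCI-H295R cells: ChIP-seq libraries for H3K27me3, EZH2, H3K27ac, SF1 and β-catenin, each at baseline and after EZH2i, and 1 input pooled from all chromatin. Per the labels' protocols, cells were grown in 8 dishes for vehicle and 16 for the inhibitor at 62 µM, and were harvested after about 96 h of drug, 120 h after plating. Chromatin was sheared to 300 to 500 bp on average, and Drosophila chromatin was added as a spike-in, per the labels. Each sample was assigned to its group from its title. Each group held 1 library, so the plates of a treatment entered the same chromatin and there is no measure of spread between cultures.

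The deposited files are 10 peak lists in broadPeak form, with 1 list per library and no list for the input. Per the submitters' processing notes, Bowtie2, deepTools 2.0 and the hg38 build were used; the peak caller, and how the spike-in entered the calls, are not given in the sources used here. The authors deposited for every peak a score, −log10 of a p-value and −log10 of a q-value; a further column held 0 throughout and was not used. The score of every peak equals the integer part of its −log10 q times 1 plus the natural logarithm of its length. The score and the −log10 values are the authors' and served only to rank and filter peaks within a list. The lowest −log10 q was 5 in the H3K27me3, EZH2 and β-catenin lists and 6 in the SF1 and H3K27ac lists. Peak edges fell on a grid of 200 bp for the histone marks and 100 bp for the proteins. The smallest gap between peaks was 20.2 kb for H3K27me3, 10.1 kb for EZH2, 1.2 kb for H3K27ac and 0.6 kb for SF1 and β-catenin, so that peak length is not comparable between epitopes. The names of 5 lists carry a fraction that no label explains: 0.4 for H3K27me3 after EZH2i, 0.98 for EZH2 at baseline, 0.73 for H3K27ac at baseline, 0.76 for SF1 at baseline and 0.64 for β-catenin after EZH2i. These may be the shares of reads kept before peak calling. If so, the numbers and covered lengths of peaks depend on that scaling, including the H3K27me3 and β-catenin lists after EZH2i, and a ratio between treatments is a ratio of calls, not of binding. The lists give no read numbers, so the depth of each library is unknown. Peaks lay on 22 autosomes and X.

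A peak counted as overlapping when it shared at least 1 bp with a peak of the other list. The retained share is the share of baseline peaks that overlap an EZH2i peak of the same epitope, and baseline-only and EZH2i-only peaks have no such partner. Shares carry exact (Clopper-Pearson) binomial 95% intervals. Length ratios carry 95% percentile intervals from 1000 resamples, with the number of peaks drawn as a Poisson count and their lengths resampled. Neighbouring peaks are not independent, and all of these intervals cover counting error only. Each share was set beside its mean over 100 circular shifts, in which the other list was moved by a random offset along each chromosome; the shifts do not preserve the distance to genes or to open chromatin. To compare retention at equal strength, shares were standardised over the 10 deciles of −log10 q of the baseline list. For SF1 and β-catenin by later acetylation, the deciles of the strongest H3K27ac peak at the site were added, with 1000 resamples of the peaks for the interval, over the cells that held both kinds of site (96.9% and 84.2% of the sites). The regions named are, for each epitope, drawn from the 5 highest-scoring baseline, baseline-only and EZH2i-only peaks, a rule fixed before the data were examined. The EZH2i-only H3K27ac peaks on former H3K27me3 were ranked in the same way, a choice made later. The overlap of EZH2 with H3K27ac, the standardisation over deciles of peak length and the retention shares by site state were also chosen after the lists were seen.

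The overlap and standardisation steps were tested on simulated data. With known retained shares planted at the 23461 SF1 sites, the largest error was 0.119 percentage points. Retained sites kept their exact baseline edges, so shifted edges and missed calls were not simulated. Separately, in random values rather than SF1 sites, a planted strength difference gave a crude gap of 26.2 percentage points and 0.857 after standardisation. The planted strength was known without error, unlike the strength of the real sites. Alternatives were the upper 50% of each list by score, equal numbers of top-scoring peaks, peaks joined across gaps of 1 kb, an overlap of at least 50% of the peak, a −log10 q of at least 6, EZH2 peaks joined across 20 kb, and only peaks of at least 1 kb. The last 3 were added after the data were seen. Planned counts of genes with promoter peaks, gene lists and sequence motifs need a human gene annotation or genome, which were not used here. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.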

Results

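Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out in NCI-H295R, an established human adrenocortical carcinoma cell line with an activating mutation in the β-catenin gene. Cells received vehicle (DMSO, called baseline) or EPZ-6438, a small molecule that blocks the catalytic activity of the histone methyltransferase EZH2, at 62 µM for about 96 h (called EZH2i). EZH2 is the enzyme of Polycomb repressive complex 2 that places methyl groups on lysine 27 of histone H3, and the series asked how its inhibition alters the epigenome of these cells. Chromatin was precipitated for 5 epitopes: the repressive mark H3K27me3, EZH2 itself, the active mark H3K27ac, steroidogenic factor 1 (SF1, the nuclear receptor that directs adrenocortical identity) and β-catenin (the transcriptional effector of Wnt signalling). Each epitope had 1 library per treatment, which gave 10 peak lists, and 1 input pooled from all chromatin. With no replicate library, no comparison between treatments was tested and no p-value is given. Intervals in parentheses are 95% intervals that cover counting error only, and the read depth of the libraries, and whether reads were subsampled before peak calling, are unknown. Positions are hg38 coordinates, and gene annotation was not used here.

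H3K27me3, the product of EZH2, was called over far less of the genome after EZH2i. Baseline cells had 10171 H3K27me3 peaks that covered 232 Mb, and cells after EZH2i had 3217 peaks that covered 29.5 Mb. The covered length was therefore 0.127 times the baseline length (0.114 to 0.140), or 87.3% lower. Long domains accounted for most of the difference: 4495 baseline peaks reached 10 kb and held 219 Mb, against 756 peaks and 25.7 Mb after EZH2i. The mean peak length was 22858 bp at baseline and 9176 bp after EZH2i. Nearly all of the residual signal lay in former domains, since 96.0% of the EZH2i peaks (95.3 to 96.7) and 99.6% of their length overlapped baseline H3K27me3, and only 128 peaks were EZH2i-only.

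Baseline H3K27me3 domains that carried EZH2 were retained more often than the others, and retained domains were also longer, with a median of 41800 bp against 3200 bp for lost domains. Of the baseline H3K27me3 peaks, 21.3% (20.5 to 22.1) overlapped a peak called after EZH2i, compared with 3.31% when the EZH2i list was shifted along the chromosomes. Baseline peaks with an EZH2 peak were retained in 58.1% of cases (56.3 to 59.96, 1660 of 2855) and those without in 6.96% (6.38 to 7.56, 509 of 7316). After standardisation for the peak's own −log10 q decile the shares were 39.6% and 7.98%, and for its length decile, which also sets the chance of an overlap, 35.8% and 11.4%. Higher retention was not particular to EZH2. Crude retention was 70.3% with β-catenin and 19.8% without, 68.7% with H3K27ac and 20.8% without, and 64% with SF1 and 19.6% without. At equal −log10 q the shares were 44.0% and 20.2% for β-catenin, 42.8% and 20.9% for H3K27ac, and 41.8% and 20.0% for SF1. These gaps at equal −log10 q were smaller than that for EZH2. They rested on 316, 115 and 405 domains with such a peak, and were not standardised for length. The 5 highest-scoring baseline domains were all retained: chr13:113729801-114233000, chr7:50956801-51381000, chr7:50252801-50409400, chr9:135297801-135460400 and chr9:133489201-133739600, each with EZH2 peaks in both treatments. All of them except chr9:135297801-135460400 also carried SF1 in both treatments and β-catenin at baseline. The 5 highest-scoring domains lost from the list were chr5:101932601-102126400, chr5:15255601-15381000, chr1:36534201-36748800, chr3:79866601-79954400 and chr3:13513401-13610400, and 3 of them had carried EZH2 at baseline. By chromosome, the share of baseline H3K27me3 length still called ranged from 1.24% on X and 2.92% on chromosome 2 to 24.1% on chromosome 7. The 5 highest EZH2i-only peaks were at most 0.6 kb long and overlapped no peak of any other list. The retained share depended on the definition: it was 2.39% when at least 50% of a baseline peak had to be covered, and 53.6% between the 3217 highest-scoring peaks of each list. Among peaks with a −log10 q of at least 6, 178 at baseline and 91 after EZH2i, it was 3.37% and the length ratio was 0.0813.

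**Figure D1:**
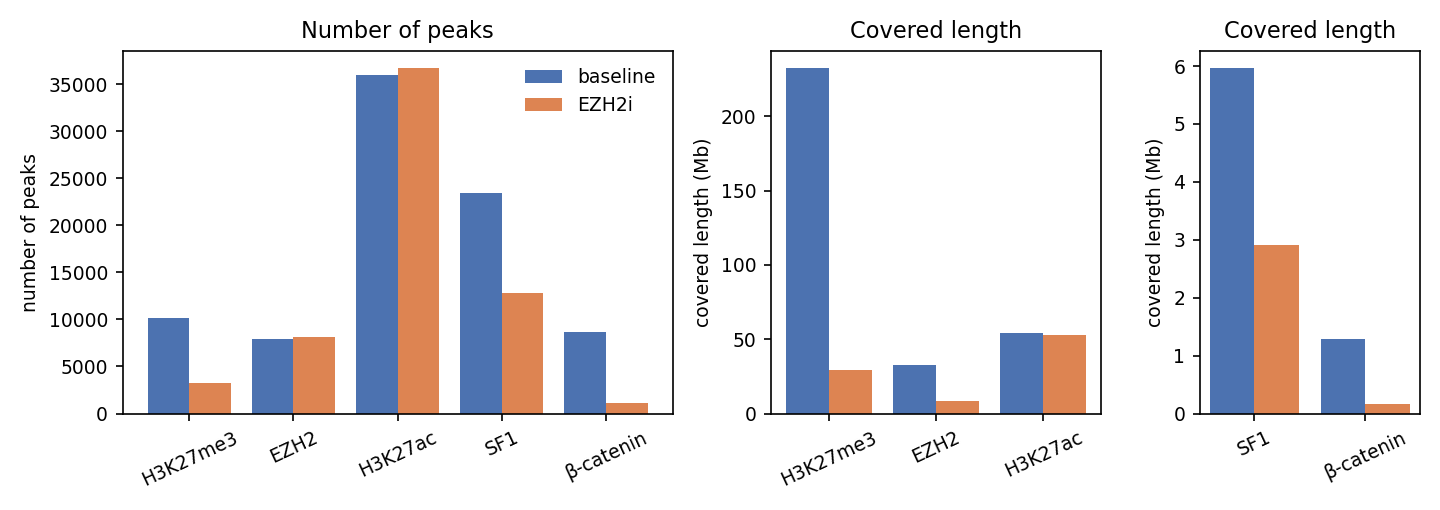
Number of peaks (left) and covered length in Mb (middle and right, on separate scales) for the 5 epitopes at baseline (blue) and after EZH2i (orange), 1 library per bar and no error bar. H3K27me3 covered 232 Mb at baseline and 29.5 Mb after EZH2i, EZH2 had 7869 and 8152 peaks over 32.6 and 8.25 Mb, and β-catenin had 8614 and 1125 peaks.

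The full EZH2 lists were of similar number, but most sites differed and long EZH2 domains were fewer after EZH2i. The lists held 7869 baseline peaks over 32.6 Mb and 8152 EZH2i peaks over 8.25 Mb, a length ratio of 0.253 (0.231 to 0.278). The balance of numbers depended on the peaks counted, with 2492 and 3844 at a −log10 q of at least 6, and 2925 and 1191 among peaks of at least 1 kb. The median peak length was 100 bp in both lists, while the mean was 4149 bp and 1012 bp, and the number of peaks of at least 10 kb was 930 and 182. Of the baseline peaks, 21.5% (20.6 to 22.4) overlapped an EZH2i peak, against 1.66% after shifting. The remaining 6179 baseline peaks were baseline-only, and 6319 EZH2i peaks were EZH2i-only. The retained share was 10.6% when at least 50% of the baseline peak had to be covered.

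The chromatin context of the EZH2 peaks differed between the treatments. At baseline, 64.4% of EZH2 peaks (63.3 to 65.5) overlapped H3K27me3 and 10.9% (10.2 to 11.6) overlapped H3K27ac. After EZH2i these shares were 12.8% (12.0 to 13.5) and 54.2% (53.1 to 55.3). Shifted lists gave 10.3% and 5.74% at baseline, and 1.48% and 3.08% after EZH2i. Measured against the baseline H3K27me3 domains, 23.5% of the EZH2i peaks (22.6 to 24.5) still lay on former H3K27me3. By length, 92.5% of the EZH2-covered sequence lay in H3K27me3 domains at baseline, and 50.4% of the EZH2i sequence lay in those baseline domains. Among EZH2 peaks of at least 1 kb the overlap with H3K27me3 was 93.4% at baseline and 43.9% after EZH2i, and the overlap with H3K27ac was 3.59% and 51.5%.

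More than 50% of the EZH2i-only EZH2 peaks lay on chromatin that was already acetylated in baseline cells. Of these 6319 peaks, 58.9% (57.7 to 60.1) overlapped a baseline H3K27ac peak, 59.6% (58.4 to 60.9) an EZH2i H3K27ac peak and 12.0% (11.2 to 12.8) baseline H3K27me3. The acetylated peaks they met were strong ones, with a median −log10 q percentile of 79.8 within the EZH2i H3K27ac list. The 5 EZH2i-only EZH2 peaks with the highest scores, chr7:44480601-44494900, chr19:1848501-1848700, chr5:140711201-140726300, chr7:55951801-55951900 and chr16:22297101-22298600, were all acetylated in both treatments and free of H3K27me3 in both. The 5 highest baseline-only EZH2 peaks, led by chr4:8639201-8666100, chr22:22177201-22187500 and chr13:111939801-111981600, all lay in H3K27me3 domains that were still called after EZH2i, and none carried H3K27ac. Of the 6179 baseline-only EZH2 peaks, 65.3% (64.1 to 66.5) overlapped baseline H3K27me3. Only 19.1% (18.2 to 20.1) overlapped H3K27me3 called after EZH2i, so these 5 do not stand for the class. Baseline EZH2 peaks on H3K27ac were retained in 68.0% of cases (64.7 to 71.1) and the others in 15.8% (15.0 to 16.7). Retention was 20.4% with H3K27me3 and 23.4% without. The peaks without it mix those on H3K27ac with 1974 baseline peaks on neither mark. Retention of the latter was not examined apart, so these 2 shares do not show the part of H3K27me3. The 5 highest-scoring baseline EZH2 peaks were all retained: chr4:119454601-119454800, chr17:43360201-43368000 and chr19:10717601-10718100, which lay on H3K27ac, chr12:130764201-130765600, which carried neither mark, and chr9:130657501-130675700, which lay in H3K27me3 in both treatments.

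H3K27ac had the highest retained share of the 5 epitopes. The lists held 35915 baseline peaks over 54.2 Mb and 36706 EZH2i peaks over 52.8 Mb, a length ratio of 0.974 (0.953 to 0.995). Of the baseline peaks, 79.2% (78.7 to 79.6) were called again, against 3.73% after shifting, and the share was 99.7% in the highest −log10 q decile and 44.1% in the lowest. The leading peaks, chr19:49949801-49959000 and chr5:398201-402400, were acetylated in both treatments and carried SF1 in both. Baseline-only peaks numbered 7485, and the 5 with the highest scores all carried a baseline SF1 peak: chr11:72130601-72133200, chr20:42863801-42866000, chr9:86012001-86013400, chr9:111455601-111458200 and chr5:177097201-177099200. The first 3 of these had no SF1 peak after EZH2i. They do not stand for the class, since baseline SF1 was present at 33.0% (31.9 to 34.1) of the baseline-only and 38.4% (37.8 to 38.9) of the retained H3K27ac peaks. The retained peaks were longer, with a mean of 1747 bp against 609 bp. At equal −log10 q the order was the opposite: H3K27ac peaks with SF1 were retained in 74.2% of cases and those without in 81.3%. EZH2i-only peaks numbered 8145, led by chr13:113820601-113822400, chr7:43571801-43573600 and chr12:19854801-19857000.

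Whether acetylation appeared in regions that had carried H3K27me3 was examined with the EZH2i-only H3K27ac peaks. Of these 8145 peaks, 501 (6.15%, 5.64 to 6.69) overlapped a baseline H3K27me3 domain. The share was 0.410% (0.339 to 0.491) for peaks acetylated in both treatments and 0.227% (0.132 to 0.363) for baseline-only peaks. Random placement gave more, 8.38% on average and 7.23% at the lowest, so EZH2i-only acetylation was not enriched in former H3K27me3 domains over random placement. The shifts do not preserve the distance to open chromatin, so a preference for former domains is neither shown nor excluded. The other classes were acetylated at baseline, where only 0.359% of H3K27ac peaks overlapped H3K27me3. Their lower shares therefore follow largely from how the classes were defined. Of the 501 peaks, 98.2% lay wholly inside a domain, and 147 lay in H3K27me3 that was still called after EZH2i. They fell in 353 domains, or 3.47% of the baseline domains. The highest-scoring example, chr13:113820601-113822400, had a β-catenin peak only after EZH2i and carried EZH2 in both treatments. The next were chr5:31962401-31964200, chr15:69760401-69761600, which had SF1 and β-catenin peaks only after EZH2i, and chr20:58129801-58133600. Within a treatment the overlap of H3K27ac with H3K27me3 was small, at 0.359% (0.300 to 0.427) at baseline and 0.460% (0.394 to 0.535) after EZH2i, where shifted lists gave 8.40% and 1.22%. In the upper 50% of each list by score these shares were 0.173% and 0.212%.

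**Figure D2:**
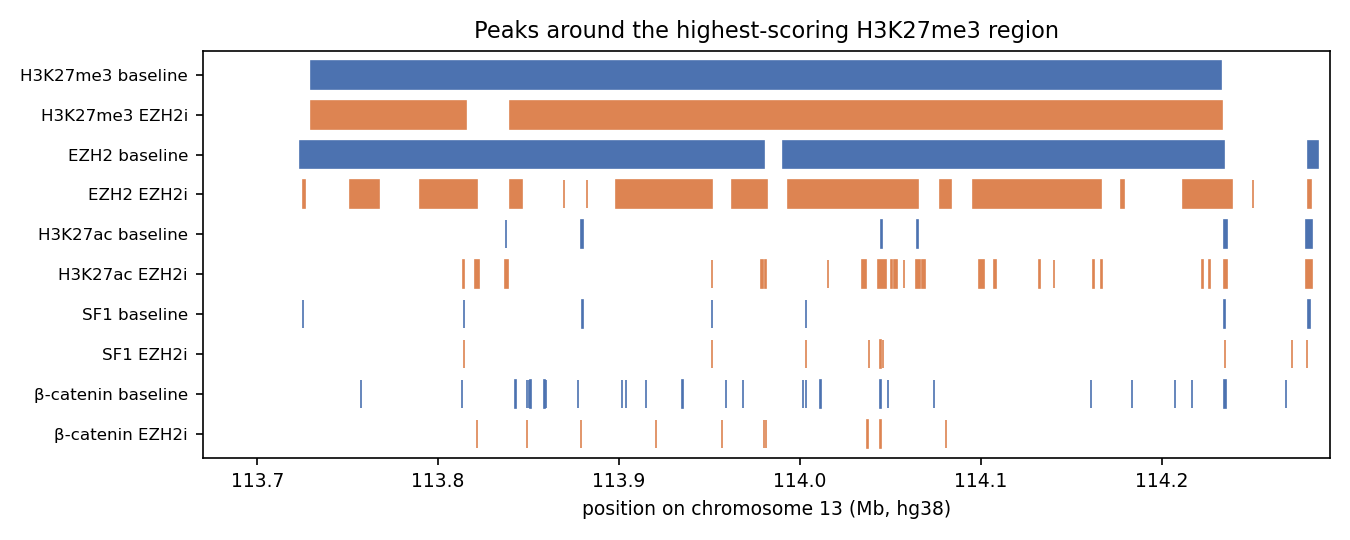
Called peaks of each list along chromosome 13 (hg38, Mb) around the highest-scoring baseline H3K27me3 domain, chr13:113729801-114233000, with baseline in blue and EZH2i in orange. Inside the domain H3K27me3 still covered 95.2% of the length after EZH2i, and EZH2 covered 97.9% at baseline and 59.2% after EZH2i. H3K27ac had 4 and 22 peaks there, β-catenin 25 and 10, and SF1 4 and 6.

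SF1 was called at fewer sites after EZH2i. The list held 23461 peaks over 5.97 Mb at baseline and 12767 peaks over 2.92 Mb after EZH2i, a length ratio of 0.489 (0.475 to 0.503). Of the baseline peaks, 41.5% (40.9 to 42.2) were called again, against 0.226% after shifting, and 94 of the 100 with the highest −log10 q were. Of the EZH2i peaks, 76.7% (75.9 to 77.4) had been present at baseline, which left 2978 EZH2i-only peaks. The 5 leading baseline sites, chr9:94951001-94951300, chr3:196055101-196056500, chr13:98240001-98240600, chr15:76184201-76184500 and chr9:114465901-114466800, were all retained, and all carried β-catenin at baseline. Among the strongest baseline-only sites, chr9:37527101-37527600 and chr9:37543601-37543900 lost SF1, β-catenin and H3K27ac together. The authors' highest −log10 q was 37.5 in the baseline list and 112 in the EZH2i list, with medians of 8.13 and 8.89, values that are not comparable between lists. The leading EZH2i-only sites were chr16:50463101-50463200 and chr3:77939901-77940000, each 100 bp long.

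SF1 retention differed with the state of the site. Baseline SF1 peaks with β-catenin were retained in 70.4% of cases (68.9 to 71.9) and those without in 36.4% (35.8 to 37.1), or 61.8% and 38.1% at equal −log10 q. On H3K27ac 49.2% were retained (48.4 to 49.98) and elsewhere 28.4% (27.4 to 29.3). Among SF1 peaks on baseline H3K27ac, 58.2% (57.3 to 59.1) were retained where acetylation was still called after EZH2i, and 20.0% (18.7 to 21.3) where it was not. In the highest decile by −log10 q these shares were 90.5% (88.8 to 91.9, 1270 of 1404) and 172 of 344 sites (44.6 to 55.4%), with 63.5% (59.3 to 67.6) at sites acetylated in neither treatment. Of all SF1 peaks, 63.4% (62.8 to 64) lay on H3K27ac at baseline and 67.4% (66.6 to 68.2) after EZH2i, against 2.26% and 2.13% after shifting. Baseline H3K27ac was present at 75.0% of the retained and 55.1% of the baseline-only SF1 peaks, and 55.2% of the EZH2i-only SF1 peaks lay on EZH2i H3K27ac. Of the 13713 lost SF1 peaks, 4750 (34.6%) lay on H3K27ac called in both treatments, 2808 (20.5%) on H3K27ac called at baseline only and 6155 (44.9%) outside baseline H3K27ac.

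**Figure D3:**
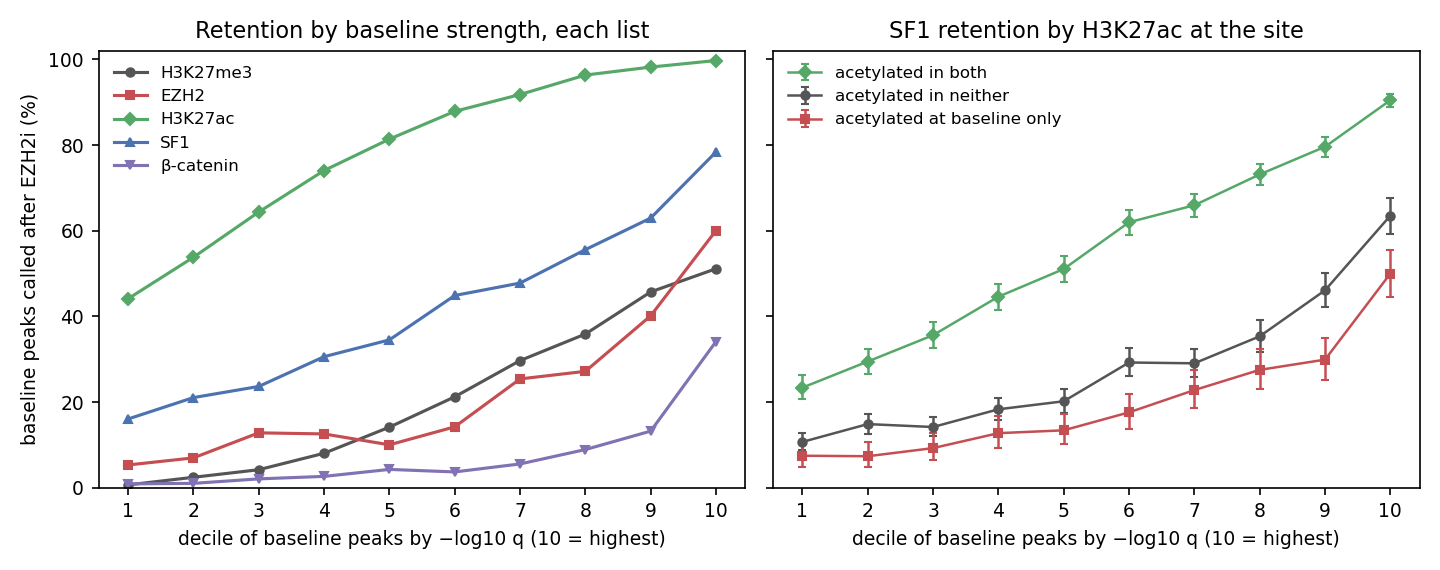
Share of baseline peaks (%) called again after EZH2i, by decile of −log10 q within the baseline list, for each epitope (left) and for SF1 peaks by H3K27ac at the site (right, bars are exact 95% binomial intervals). In the highest SF1 decile 90.5% were called again at sites acetylated in both treatments, against 172 of 344 sites acetylated at baseline only.

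β-catenin showed the sharpest reduction in peak number. The list held 8614 peaks over 1.29 Mb at baseline and 1125 peaks over 0.163 Mb after EZH2i, a length ratio of 0.126 (0.116 to 0.136). Of the baseline peaks, 7.66% (7.11 to 8.24) were called again, against 0.0136% after shifting, and 68 of the 100 with the highest −log10 q were. Leading sites that were retained included chr4:38570801-38571300, chr3:196055701-196056200, chr10:100881301-100881600 and chr9:109414501-109414700. The highest-scoring sites that were lost, chr1:108865701-108865900, chr6:137900901-137901200, chr10:61067001-61067200, chr15:79881401-79881900 and chr21:40071001-40071200, all remained acetylated, and all except the one on chromosome 10 kept SF1. Of all 7954 baseline-only β-catenin peaks, 54.6% (53.5 to 55.7) carried H3K27ac and 25.5% (24.6 to 26.5) carried SF1 after EZH2i. EZH2i-only peaks numbered 463, led by chr1:170714201-170714400. Between the 1125 highest-scoring peaks of each list the retained share was 34.6% and the length ratio 0.547.

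The β-catenin peaks called after EZH2i lay at SF1 sites and acetylated sites in larger shares than those at baseline. The share of β-catenin peaks with SF1 was 41.3% (40.3 to 42.3) at baseline and 50.8% (47.9 to 53.8) after EZH2i, and shifted lists gave 0.371% and 0.191%. The share on H3K27ac was 60.7% (59.7 to 61.8) and 75.1% (72.5 to 77.6), against 2.19% and 2.02%. Both shares were higher among peaks with a −log10 q of at least 6, at 57.4% and 62.9% with SF1, and 73.1% and 85.2% on H3K27ac. Equal numbers of peaks were not compared for these overlaps. The larger shares after EZH2i may therefore reflect only which weak peaks entered each list. Baseline β-catenin peaks with SF1 were retained in 13.9% of cases (12.7 to 15.0) and those without in 3.30% (2.83 to 3.83), or 9.92% and 5.22% at equal −log10 q. Of the 3557 baseline β-catenin peaks with SF1, 440 (12.4%) kept both proteins, 1860 (52.3%) kept SF1 alone, 53 (1.49%) kept β-catenin alone and 1204 (33.8%) kept neither. Acetylation persisted at most of these joint sites: 3058 were on H3K27ac at baseline, and 2742 of those (89.7%) were on H3K27ac after EZH2i. Seen from SF1, 15.1% of peaks (14.6 to 15.5) carried β-catenin at baseline and 4.46% (4.11 to 4.83) after EZH2i. The shorter β-catenin list lowers this share by itself, and shifted lists gave 0.133% and 0.0159%, so the observed share was 113 and 280 times the shifted one. The shifts do not preserve the distance to open chromatin, so the larger ratio alone does not show closer co-occupancy.

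**Figure D4:**
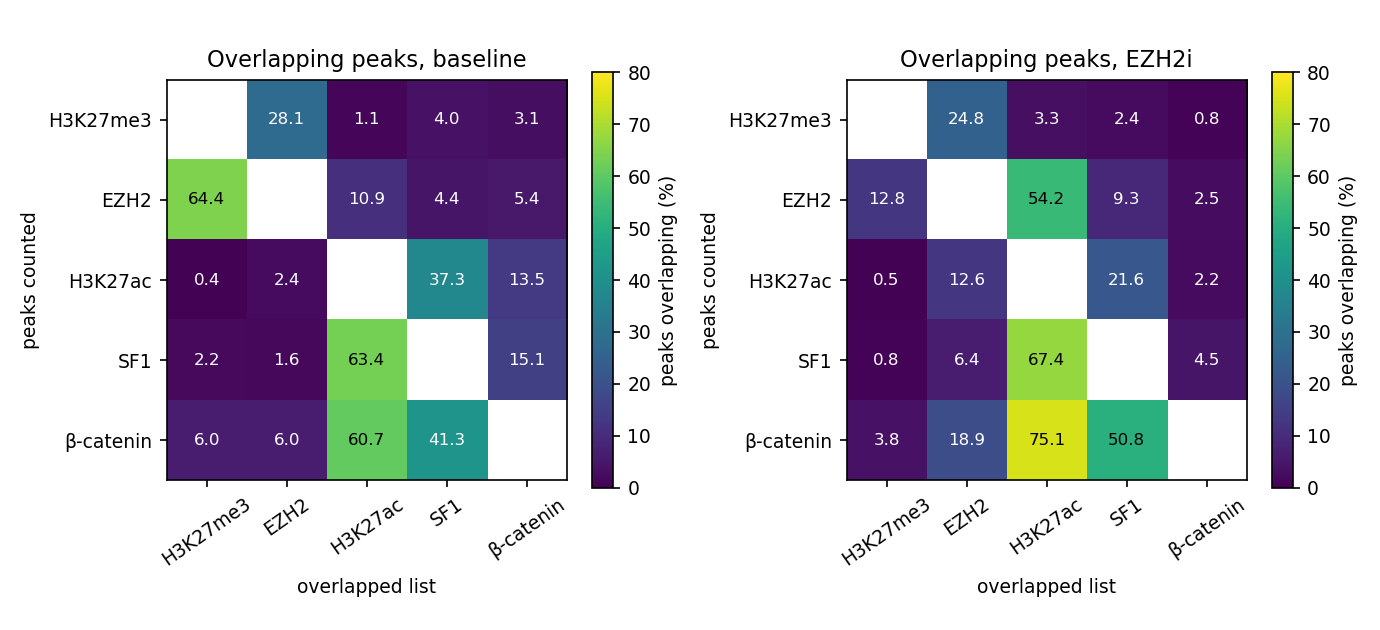
Share of the peaks of each list (rows, %) that overlap a peak of another list of the same treatment (columns) by at least 1 bp, at baseline (left) and after EZH2i (right), 1 library per list. EZH2 peaks overlapped H3K27me3 in 64.4% and H3K27ac in 10.9% of cases at baseline, and in 12.8% and 54.2% after EZH2i.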

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

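Alternatives with −log10 q of at least 6, with peaks of at least 1 kb or with gaps of 20 kb, and all for EZH2 on H3K27ac and for equal length, were chosen after the data were seen. All 18 alternative length ratios stayed below 1, so none of them reversed. A reversal was scored only for these ratios. Of all 75 alternatives, 20 stayed within the interval of the value reported and 55 did not. The cause was not tested except where fewer or shorter peaks entered by construction. Retained shares in the upper 50% by score were 22.6% for H3K27me3, 28.2% for EZH2, 77.4% for H3K27ac, 40.6% for SF1 and 9.59% for β-catenin. Between equal numbers of top-scoring peaks they were 53.6% for H3K27me3, 78.6% for H3K27ac, 59.0% for SF1 and 34.6% for β-catenin, with length ratios of 0.149 for H3K27me3, 0.687 for SF1 and 0.547 for β-catenin. Requiring 50% of the baseline peak gave 2.39% for H3K27me3, 10.6% for EZH2, 71.8% for H3K27ac, 33.9% for SF1 and 5.22% for β-catenin. Joining SF1 peaks across 1 kb gave 42.2%, and joining EZH2 peaks across 20 kb gave 25.7% and a length ratio of 0.326. A −log10 q of at least 6 gave retained shares of 3.37% for H3K27me3, 28.3% for EZH2 and 9.70% for β-catenin, with length ratios of 0.0813 for H3K27me3 and 0.140 for β-catenin. Peaks of at least 1 kb gave 16.1% for H3K27me3 and 18.2% for EZH2, with an EZH2 length ratio of 0.221.

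Overlaps are given as baseline, then EZH2i. In the upper 50% by score, SF1 on H3K27ac was 53.3% and 58.9%, β-catenin on SF1 46.5% and 54.9%, β-catenin on H3K27ac 65.1% and 83.5%, EZH2 on H3K27me3 76.7% and 16.4%, EZH2 on H3K27ac 9.07% and 56.1%, and H3K27ac on H3K27me3 0.173% and 0.212%. An overlap of 50% of the peak gave 62.5% for SF1 on H3K27ac and 39.4% for β-catenin on SF1 at baseline, 62.8% and 11.4% for EZH2 on H3K27me3, and 9.90% and 50.1% for EZH2 on H3K27ac. EZH2 peaks of at least 1 kb gave 93.4% and 43.9% on H3K27me3, and 3.59% and 51.5% on H3K27ac. β-catenin peaks with a −log10 q of at least 6 gave 57.4% and 62.9% on SF1, and 73.1% and 85.2% on H3K27ac. Each of these pairs kept its order. The gap in H3K27me3 retention with and without EZH2 was 31.6 percentage points at equal −log10 q and 24.4 at equal length. Joining across 1 kb cannot alter the H3K27me3, EZH2 and H3K27ac lists, and restriction to autosomes and X removes nothing, so these were not run. Promoter counts, gene lists and motif shares were not run without a human annotation or genome. Unknown depth and the lack of replicates limit every comparison between treatments.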

Other observations

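The tests of a uniform drop in SF1 and β-catenin sensitivity, that of loss of called acetylation as the whole cause, and the comparison of other epitopes across chromosomes, were chosen after the result was seen. Beyond the comparisons above, acetylation was examined from the side of the H3K27ac peaks. Baseline H3K27ac peaks with at least 1 retained SF1 site were acetylated after EZH2i in 93.2% of cases (92.5 to 93.7, 6409 of 6880), and those with only lost SF1 sites in 69.3% (68.1 to 70.4, 4502 of 6501), or 91.4% and 73.8% at equal −log10 q. For β-catenin the shares were 550 of 550 and 94.5% (93.8 to 95.2, 4075 of 4312). SF1 occupancy by itself went with higher retention of H3K27ac in the crude shares, at 81.5% with SF1 and 77.7% without, but at equal −log10 q of the H3K27ac peak the order was the opposite, 74.2% with SF1 and 81.3% without. H3K27ac peaks with β-catenin were retained in 95.1% of cases and those without in 76.7%, and at equal −log10 q the gap was smaller, at 87.3% against 78.6%.

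β-catenin and EZH2 overlapped more often relative to shifted lists after EZH2i. EZH2 overlapped 5.96% of the β-catenin peaks at baseline (5.46 to 6.48) and 18.9% after EZH2i (16.7 to 21.3), while shifted lists gave 1.40% and 0.451%. Seen from EZH2, β-catenin overlapped 5.43% of peaks at baseline and 2.53% after EZH2i, where the β-catenin list was shorter and shifted lists gave 1.30% and 0.0590%. Relative to shifting, the overlap was 4.25 and 42.0 times as frequent from the β-catenin side, and 4.16 and 42.8 times from the EZH2 side. Because the shifts do not preserve the distance to open chromatin, these ratios alone do not show closer co-occupancy. The baseline β-catenin peaks already overlapped the EZH2i EZH2 list in 14.8% of cases. Of the 463 EZH2i-only β-catenin peaks, 76 (16.4%, 13.2 to 20.1) lay in baseline H3K27me3 domains, against 7.10% (5.26 to 9.33) of the EZH2i peaks present in both treatments. For SF1 the corresponding shares were 6.31% (5.47 to 7.25, 188 of 2978) and 2.59% (2.29 to 2.93). Shifting gave 8.95% for the whole baseline β-catenin list and 8.41% for that of SF1, but the EZH2i-only peaks were not shifted. The peaks present in both treatments were called at baseline, where 5.98% of β-catenin and 2.18% of SF1 peaks overlapped H3K27me3. Their lower shares may therefore follow partly from how the classes were defined.

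The different overlap of EZH2 peaks with H3K27me3 and H3K27ac between the treatments was weighed against 3 technical explanations. A shrinking H3K27me3 list over a fixed EZH2 list would leave the overlap with baseline H3K27me3 near its baseline 64.4%, but it was 23.5%. Shorter EZH2 peaks after EZH2i do not account for it either, because among EZH2 peaks of at most 1 kb the overlap with baseline H3K27me3 was 47.5% at baseline and 18.9% after EZH2i. Non-specific recovery of strongly acetylated, open chromatin remains open: the H3K27ac peaks met by EZH2i-only EZH2 peaks had a median −log10 q percentile of 79.8 within their list, and the share of H3K27ac peaks with EZH2 climbed from 1.77% in the lowest decile to 37.4% in the highest after EZH2i, and from 0.223% to 7.38% at baseline. Redistribution of EZH2 under the inhibitor may produce the same gradient, and these lists do not separate the explanations.

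The smaller SF1 and β-catenin lists could come from less sensitive EZH2i libraries. The unexplained fraction in the names is on the baseline list for SF1 (0.76) and on the EZH2i list for β-catenin (0.64). If it is a share of reads kept, the reduction fell on opposite sides for SF1 and β-catenin. A uniform loss of sensitivity would retain SF1 sites of equal true strength alike. At equal −log10 q of both the SF1 peak and its H3K27ac peak, sites that stayed acetylated were retained 39.1 percentage points more often than sites that did not (35.9 to 41.0). For β-catenin this difference was 9.87 percentage points (8.29 to 10.7), and with −log10 q of the SF1 or β-catenin peak alone the differences were 36.6 and 11.4; these replaced earlier tests on the 100 strongest peaks, of which 94 for SF1 fell between the bounds set and 68 for β-catenin met the bound against, but which decide nothing. The alternative that SF1 was lost where acetylation was lost gave a standardised difference in H3K27ac retention of 17.5 percentage points between peaks with retained and with only lost SF1 sites. This is the same association seen from the H3K27ac side. Loss of the H3K27ac call cannot be the whole cause. Only 20.5% of the lost SF1 peaks (19.8 to 21.2) and 519 of the 7954 lost β-catenin peaks lay on H3K27ac called at baseline only. A lower level of acetylation under a peak that was still called cannot be seen in these lists and stays open. The order of events, a loss of sensitivity that is uniform or differs between kinds of chromatin, and a partial contribution of depth stay open.

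Retention of H3K27me3 was uneven between chromosomes: the share of baseline H3K27me3 length still called was 24.1% on chromosome 7, 22.3% on chromosome 12 and 22.1% on chromosome 13, and 2.92% on chromosome 2 and 1.24% on X. Across the 23 chromosomes, which are not independent replicates, it followed the density of baseline β-catenin peaks relative to H3K27ac peaks (Spearman rho 0.762, and 0.703 without chromosomes 7 and 9). A property shared by all libraries that raises detection, such as copy number, could give this, and the rho reached the first value set for that property. The measure divides β-catenin density by H3K27ac density, so such a property may partly cancel in it. Reaching the value therefore does not by itself speak for the property. A requirement on the length still called of each other epitope was added later. SF1, H3K27ac and EZH2 met it, with a rho of 0.435, 0.416 and 0.251, and β-catenin did not, at 0.0178. The retained share was not part of that requirement. Its rho was 0.484 for SF1, 0.432 for H3K27ac, −0.227 for EZH2 and −0.0494 for β-catenin. The explanation therefore stays open. Density of active chromatin, measured as H3K27ac peaks per Mb, gave a rho of 0.339, between the values set for and against it. Copy number was not measured here, and no explanation tied to the treatment was tested for this pattern.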
